A study of Homo sapiens with 4 samples.

How the data were processed

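Chromatin accessibility was measured by ATAC-seq in 4 libraries of the lymphoma line TMD8. Per the labels' protocols, intact nuclei were treated with a transposase, and the tagged DNA was indexed, amplified and sequenced on a HiSeq4000. The labels place 2 libraries in a control group, which the design text describes as a scrambled short hairpin RNA (shRNA), and 2 in a group with an shRNA against IRF4 (shIRF4). The sample titles say shIRF4 while the library names say siIRF4, and the title and design text were followed.

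The deposited files hold raw read counts per merged peak, here called intervals, made by the authors with featureCounts 2.0.0, per the file headers. The headers show that each read was reduced to its 5' end, that reads marked as duplicates were ignored, that the libraries were read as paired-end, and that fractions of multi-mapping reads were requested. All counts were nevertheless whole numbers (0 non-integer counts). The genome build was hg38, per the submitters' processing notes. The aligner, the peak caller and whether read ends were shifted for the transposase's offset were not given in the sources used here. A missing shift moves a cut site by a few bases and is small against the intervals, whose median length was 552 bp (shortest 105 bp, longest 98362 bp). Ignoring duplicates caps the count of short, densely read intervals, and more so in a deeper library. The same 73135 intervals were counted in all 4 libraries. Their numbers run to 73558, and the 423 numbers not present were not analysed here.

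Interval counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Intervals with too few counts were removed by filterByExpr with the group as design, which left 73028 intervals and removed 107. Library sizes were scaled with TMM factors, which lay between 0.981 and 1.03. Differences were tested with the edgeR quasi-likelihood F-test (glmQLFit with legacy=FALSE and robust=FALSE, two-sided) on all 4 libraries with the group as the only term. P-values were adjusted by Benjamini and Hochberg (BH) over all tested intervals, with a threshold of 0.05. "Higher", "lower", "rose" and "fell" refer to intervals past that threshold in shIRF4 against control. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM values (read counts relative to the library size, scaled with the TMM factors), given as mean ± SD over 2 libraries. The precision was checked on simulated data: among 73018 intervals drawn from the real means and library sizes, with 200 changed, the test recovered 37% of 1.5-fold and 84% of 2-fold changes, called 5 unchanged intervals and gave 0 wrong signs. The simulation covers counting and model error only. It changed far fewer intervals than were called in the real data. Its adjusted threshold was therefore stricter, and its recovery rates need not hold there.

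Gene names came from a RefSeq gene table of the same build that holds gene starts and ends without strand, and no genome sequence was used here. The design written beforehand assigned each interval to the nearest transcription start site and defined promoters by it. Without strand, each interval was instead assigned to the protein-coding gene whose body holds its midpoint, and otherwise to the gene with the nearest end within 100 kb. An interval within 1 kb of either end of a protein-coding gene is called a gene-end interval, so that starts and ends of genes are not told apart. Of the 73135 intervals, 65302 were assigned, 7833 were not, and 12787 were gene-end intervals. Assignment by position does not show which gene an interval regulates. Tests of 23 sequence motifs and corrections for GC content were not run, because they need the genome sequence.

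Gene lists were fixed before the data were examined: 18 lists with 270 distinct genes, some of them in more than 1 list, of which 269 were in the gene table. They cover IRF4 and its partner factors, signatures of activated B cell-like (ABC) and germinal centre B cell-like (GCB) lymphoma, the plasma cell program, NF-kB targets, the type I interferon response, B cell receptor (BCR) and MYD88 signalling, B cell identity, MHC class II, MYC and the cell cycle, cell death regulators, p53 targets, and the unfolded protein and stress response. Comparison lists hold T cell, NK cell, myeloid, and epithelial and fibroblast markers, and housekeeping genes. Each list was tested with camera on its intervals with a preset correlation of 0.01 (two-sided, BH over 18 lists). The genes named in the text follow a rule also fixed beforehand. It takes every interval assigned to IRF4. It takes the 10 intervals with the largest rise and the 10 with the largest fall among called intervals at or above the median abundance whose groups do not overlap, with the interval of smallest p kept per gene. Intervals assigned to no gene, those on chromosome Y, and those assigned to immunoglobulin or T cell receptor segments or to genes without a symbol of their own, were left out of this choice. It takes up to 4 genes per list and 2 per comparison list by smallest p. Other genes appear with their number of called intervals only, or are said to have been chosen after their values were seen. Whether changed intervals lie at gene ends was tested with Fisher's exact test (two-sided).

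The labels do not say that libraries of 1 group came from separate cultures. P-values then measure only the spread between these libraries, which may be technical. The counts of the control pair were compared by a chi-square test before they were used as replicates. Library totals ranged from 9112860 to 17954924, and a count of 3 in the shallowest library corresponds to 0.329 CPM. Alternatives fixed beforehand were DESeq2 1.42.0, other library scalings, filters, thresholds and fits, limma-voom, a replicate block, and leaving out each library in turn; for gene lists also fry, an estimated correlation, other assignments and counts summed per gene. Alternatives added after the data were examined were the control pair as 1 sample, libraries thinned to the smallest total, offsets trended by read density, intervals of at most 5 kb, a test against a 1.5-fold change (glmTreat), omission of chromosomes 19 and Y, and assignment to the nearest gene end. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.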

Results

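Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags DNA that is free of nucleosomes, in TMD8 cells. TMD8 is an established cell line of ABC-type diffuse large B cell lymphoma. IRF4, the silenced gene, encodes a transcription factor that drives plasma cell differentiation and on which ABC lymphoma cells depend. The data comprised 2 control libraries and 2 shIRF4 libraries. The total count over all intervals was 12152153 and 13609123 in the control libraries and 17954924 and 9112860 in the shIRF4 libraries. Over intervals, log2 CPM correlated at r = 0.984 between the control libraries, at r = 0.977 between the shIRF4 libraries, and at r = 0.927 to 0.941 between the groups; intervals are not independent replicates. The control pair differed by little more than sampling noise (chi-square per degree of freedom 1.04, p = 1.77e-16 over 73135 intervals), while the shIRF4 pair differed more (2.01 per degree of freedom). Each library was kept as a replicate (n = 2 per group).

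The single comparison of the design asks how accessibility differs between TMD8 cells with silenced IRF4 and control cells. At the IRF4 gene itself on chromosome 6, 15 intervals were assigned and 2 were lower in shIRF4. The interval at 434659 to 435008, 23390 bp outside the gene, fell from 4.55 ± 0.618 to 1.90 ± 0.532 CPM (SD, n = 2; log2 fold change -1.17, SE 0.24, adjusted p = 0.000842, edgeR). The interval at 371015 to 374332, 19079 bp outside the gene on its other side, fell from 52.8 ± 1.86 to 44.2 ± 3.61 CPM (-0.27, SE 0.07, adjusted p = 0.0106, edgeR). A gene-end interval at 390678 to 394420 lay at 54.1 ± 2.44 CPM in control and 52.1 ± 2.59 CPM in shIRF4, a difference that did not pass (-0.05, adjusted p = 0.684, edgeR). None of the other 12 intervals passed, among them the gene-end intervals at 411482 (-0.09) and 411837 (-0.31). Accessibility of IRF4 DNA does not measure its mRNA, so these values do not check the knockdown. The call at 371015 was lost without control replicate 1 (-0.23, adjusted p = 0.144), without shIRF4 replicate 1 (-0.16, adjusted p = 0.193) and in DESeq2 (-0.25, adjusted p = 0.344); without shIRF4 replicate 1 the intervals at 376900 and 398455 were called lower, and without shIRF4 replicate 2 the interval at 414487 was called higher.

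Across the genome, loss of accessibility was more frequent than gain. In shIRF4, 11338 intervals were lower and 5301 higher, together 22.8% of the 73028 tested. The lower intervals were assigned to 4646 genes and had a median fold of 1.63, and 2852 of them changed at least 2-fold. The higher intervals were assigned to 3209 genes and had a median fold of 1.60, with 819 changed at least 2-fold. Lower intervals made up 68.1% of the changed ones, and 58.0% (9926 lower, 7181 higher) when libraries were scaled by their totals only. DESeq2 called 4570 intervals (3714 lower, 856 higher), and against a 1.5-fold change 2886 were called (2419 lower, 467 higher). Leaving out a library gave 9012 without shIRF4 replicate 1, 10573 without control replicate 1, 10943 without control replicate 2 and 19960 without shIRF4 replicate 2, and with the control pair counted as 1 sample 13654 were called.

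**Figure D1:**
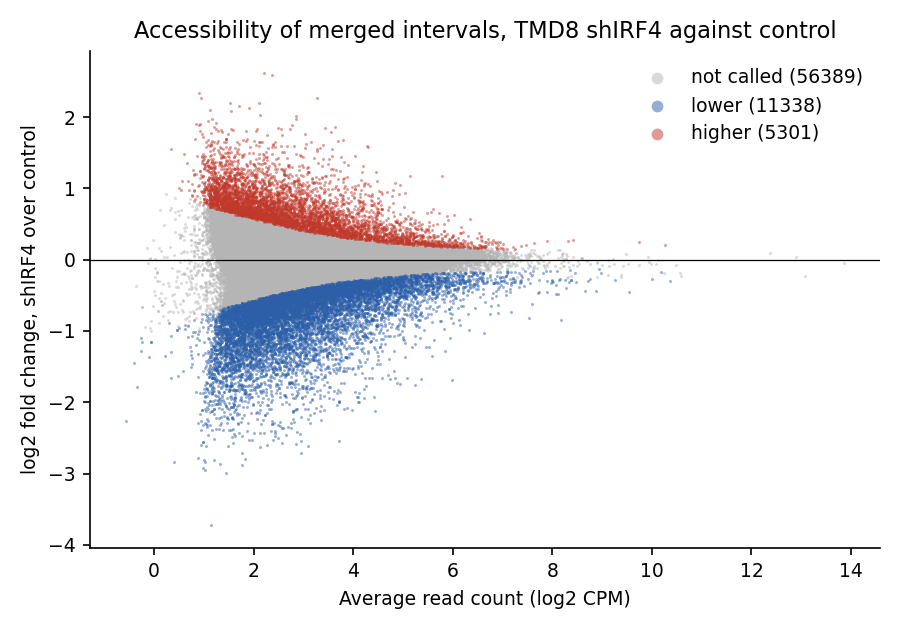
Log2 fold change (shIRF4 over control, y axis) against average log2 CPM (x axis) for the 73028 tested intervals, 1 point each, over 2 libraries per group. Blue points are the 11338 lower and red points the 5301 higher intervals; the remaining 56389, in grey, did not pass the adjusted threshold of 0.05.

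Among called intervals assigned to a gene and at or above the median abundance, with the smallest p taken per gene, the largest falls lay in or near LARS1, BRIP1, GRM5 and ELL2. An interval in the body of LARS1, a leucyl-tRNA synthetase gene, on chromosome 5 (146173546 to 146174164) fell from 13.4 ± 0.0222 to 2.07 ± 0.161 CPM (SD, n = 2; log2 fold change -2.72, SE 0.17, adjusted p = 4.57e-10, edgeR). In BRIP1, which encodes a helicase that binds BRCA1, the interval on chromosome 17 (61783805 to 61784835) changed by -2.61 (SE 0.18). The interval assigned to GRM5, a glutamate receptor gene 69090 bp away, changed by -2.58 (SE 0.20). ELL2 encodes an elongation factor that promotes the secreted form of immunoglobulin mRNA in plasma cells. Its intragenic interval on chromosome 5 (95927883 to 95928625) fell from 13.3 ± 0.492 to 2.53 ± 1.20 CPM (-2.55, SE 0.20, adjusted p = 6.19e-09, edgeR). Falls between -2.45 and -2.21 followed in or near EDRF1, WDFY4, PGBD3, MYO3B, ZNF519 and the readthrough locus FAM47E-STBD1.

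Among called intervals assigned to a gene and at or above the median abundance, again with the smallest p taken per gene, the largest gain lay between genes on chromosome 3 (46110763 to 46111506), 25290 bp from XCR1, a chemokine receptor gene of dendritic cells. It rose from 3.25 ± 0.387 to 15.3 ± 1.56 CPM (SD, n = 2; log2 fold change 2.26, SE 0.16, adjusted p = 1.64e-09, edgeR). Of the 11 intervals assigned to XCR1, 2 were higher and 3 lower. One in the gene body (46059047 to 46059860), singled out after its values were seen, fell from 10.2 ± 0.195 to 1.82 ± 0.506 CPM (-2.57, SE 0.20, adjusted p = 6.64e-09, edgeR). An interval in the readthrough locus TPTEP2-CSNK1E, which spans the casein kinase gene CSNK1E, rose by 2.01 (SE 0.19). TSPAN33, a tetraspanin gene of activated B cells, had an interval 7416 bp away that rose by 1.98 (SE 0.19). An interval inside PLEC, which encodes the cytoskeletal linker plectin, rose from 4.52 ± 0.230 to 16.5 ± 0.479 CPM (1.85, SE 0.14). Rises between 1.61 and 1.88 were also found in or near OTOF, VRK2, UBXN11, MGAT5B, PIP4K2A and CEP250.

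In the type I interferon response, 22 of 64 intervals at 21 genes were higher, 4 were lower and 38 were not called (23 higher and 6 lower adjusted over the list alone), and 15 genes had at least 1 higher interval. The list passed as higher (camera, adjusted p = 0.00145, median log2 fold change 0.20). It did not pass with an estimated correlation (camera, adjusted p = 0.376), a setting with too few degrees of freedom to decide this. At gene ends, 12 of 20 intervals were higher and 1 was lower. IFIT3, an antiviral protein gene, had a gene-end interval on chromosome 10 (89327754 to 89328376) that rose from 2.03 ± 0.385 to 6.42 ± 0.286 CPM (SD, n = 2; log2 fold change 1.66, SE 0.21, adjusted p = 5.53e-06, edgeR). MX1, a dynamin-like antiviral GTPase gene, rose at 4 of 5 intervals, by 1.05 (SE 0.15) at 41459631 to 41461269 on chromosome 21. The gene-end interval of OASL, of the oligoadenylate synthetase family, rose by 1.00 (SE 0.15). At IFI6, 3 of 4 intervals were higher. In contrast, an interval in the body of OAS2 on chromosome 12 (112998672 to 112999913) fell from 44.2 ± 0.375 to 20.4 ± 1.11 CPM (-1.13, SE 0.08), beside 1 higher OAS2 interval.

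In the plasma cell program, 22 of 103 intervals were lower and 3 higher (24 and 3 adjusted over the list alone), and 10 of 17 genes had a lower interval. Of all 73028 tested intervals, 11338 were lower and 5301 higher. A gene with many intervals may thus hold a lower one by that rate alone. The list passed as lower (camera, adjusted p = 0.0201, median log2 fold change -0.06, and -0.13 to -0.08 with 1 library left out). It did not pass with an estimated correlation (camera, adjusted p = 0.376), a setting with too few degrees of freedom to decide this. Besides ELL2, an interval 54518 bp from SEC11C, a signal peptidase subunit gene, fell from 25.05 ± 1.61 to 9.17 ± 1.53 CPM (SD, n = 2; log2 fold change -1.50, SE 0.12). Intervals in CREB3L2, which encodes a transcription factor of the secretory pathway, and 2048 bp from XBP1, the transcription factor of the plasma cell unfolded protein response, changed by -1.07 (SE 0.12) and -0.92 (SE 0.12). HSP90B1, SLAMF7, MZB1, TXNDC5 and DERL3 also had lower intervals. At CD38, 2 of 5 intervals were higher, and none of the 9 at PRDM1 or the 5 at SDC1 passed. The call of the list was lost without control replicate 2 (adjusted p = 0.0789), without shIRF4 replicate 2 (adjusted p = 0.0691), within 50 kb (adjusted p = 0.0738) and at gene ends only (adjusted p = 0.348).

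Of the lists for the 2 lymphoma subtypes, the GCB signature passed as higher and the ABC signature did not pass; the difference between them was not tested. Of the 157 intervals of the GCB lymphoma signature, 37 were higher and 19 lower (39 and 20 adjusted over the list alone). The list passed as higher (camera, adjusted p = 0.00605, median log2 fold change 0.18, and 0.09 to 0.22 with 1 library left out). It did not pass with an estimated correlation (camera, adjusted p = 0.552), a setting with few degrees of freedom. ITPKB, an inositol phosphate kinase gene, held 10 of the higher intervals, with a rise from 46.6 ± 0.551 to 71.0 ± 6.65 CPM (SD, n = 2; 0.62, SE 0.07) at 226662700 to 226663708 on chromosome 1. NEK6 held 9, with a rise of 0.90 (SE 0.12), and S1PR2, a receptor gene of germinal centre B cells, held 5. Other GCB genes had lower intervals: intervals near ASB13 and in SERPINA9, a serpin gene of germinal centre B cells, changed by -1.72 (SE 0.17) and -1.21 (SE 0.17), and 2 of 3 at MME, which encodes CD10, were lower. Of the 16 GCB genes, 9 had a higher and 9 a lower interval, with 4 in both counts. The GCB list did not pass at gene ends only (adjusted p = 0.317) or with counts summed per gene (adjusted p = 0.637). Nor did it pass by fry, which tests a list against no change and not against the other intervals (adjusted p = 0.224). In the ABC lymphoma signature, 69 of 316 intervals were lower and 23 higher (75 and 30 adjusted over the list alone). Of its 21 genes, 17 had a lower and 10 a higher interval, with 8 in both counts. The list did not pass (camera, adjusted p = 0.250), but it passed as lower with counts summed per gene (adjusted p = 0.00214) and by fry (adjusted p = 0.0374). Among its members, intervals in FOXP1 (-1.24, SE 0.11), a B cell transcription factor gene, and in IL16 (-0.80, SE 0.10) fell, as did 8 of 27 at PTPN1.

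**Figure D2:**
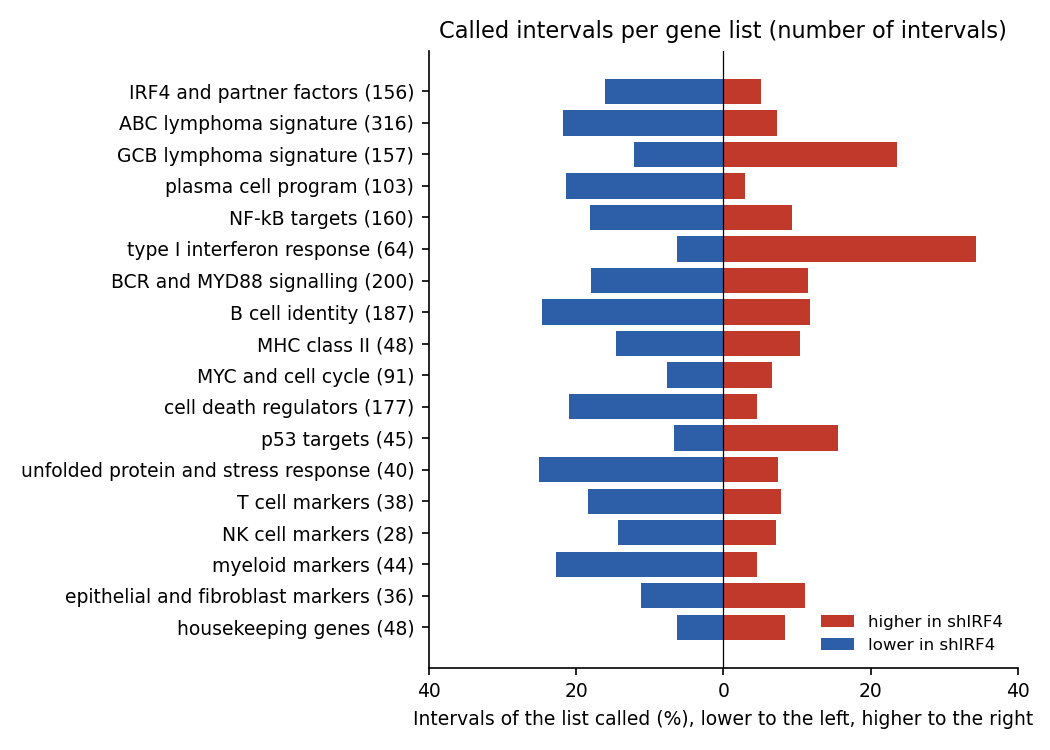
Percent of each list's intervals that were lower (blue, to the left) or higher (red, to the right) in shIRF4, with the number of tested intervals in brackets. In the type I interferon response 22 of 64 were higher and 4 lower, and in the plasma cell program 3 of 103 were higher and 22 lower. Of all 73028 tested intervals, 5301 were higher and 11338 lower, which is not drawn.

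IRF4's partner factors and B cell identity genes had more lower than higher intervals, and neither list passed with all 4 libraries. All tested intervals together also had more lower (11338) than higher ones (5301). For IRF4 and partner factors, 25 of 156 intervals were lower and 8 higher (25 and 8 adjusted over the list alone; camera, adjusted p = 0.462), and the list passed as lower without shIRF4 replicate 1 (adjusted p = 0.0397). Intervals fell near IKZF1 (-1.13, SE 0.12), in IKZF3 (-1.51, SE 0.19), both lymphoid zinc finger factors, in POU2AF1 (-1.18, SE 0.16), a coactivator of octamer factors, and near BATF3 (-0.95, SE 0.18), while 3 of 18 at IRF8 were higher. For B cell identity, 46 of 187 were lower and 22 higher (50 and 24 adjusted over the list alone; camera, adjusted p = 0.583). EBF1 went both ways, with 10 of 38 intervals higher and 5 lower, among them an intragenic interval that fell (-1.26, SE 0.09). Intervals in PAX5 (-0.52, SE 0.06), the B cell commitment factor, and FCRL1 (-0.66, SE 0.08) fell. At TCF3, 18 of 24 intervals were lower (-0.71, SE 0.07 at 1663158 to 1666390). However, TCF3 lies in a stretch of chromosome 19 where the median interval changed by -0.25, and the only SPIB interval lies in another such stretch. Against the control mean, the median of the TCF3 stretch was -0.31 in shIRF4 replicate 1 and -0.14 in replicate 2.

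Cell death regulators, NF-kB targets and signalling genes had more lower than higher intervals, and none of these lists passed. All tested intervals together leaned the same way (11338 lower and 5301 higher), so the lean is not particular to these lists. Among cell death regulators, 37 of 177 intervals were lower and 8 higher (38 and 9 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.0787); it passed as lower by fry (adjusted p = 0.0220), without chromosomes 19 and Y (adjusted p = 0.0348) and without shIRF4 replicate 1 (adjusted p = 0.0166). BCL2, the antiapoptotic gene, held 16 of the lower intervals among its 46. Its intragenic interval on chromosome 18 (63311286 to 63313753) fell from 69.4 ± 1.21 to 27.0 ± 0.716 CPM (SD, n = 2; log2 fold change -1.36, SE 0.07, adjusted p = 3.37e-11, edgeR). Intervals in the antiapoptotic gene BCL2L1 (-1.36, SE 0.13), in the proapoptotic gene BCL2L11 (-0.48, SE 0.06) and near the proapoptotic gene BMF (-0.84, SE 0.11) also fell. Among NF-kB targets 29 of 160 intervals were lower and 15 higher (30 and 16 adjusted over the list alone; camera, adjusted p = 0.831), with falls 38708 bp from TNFAIP3 (-2.26, SE 0.20), an NF-kB inhibitor gene at which 7 of 12 were lower, in CFLAR (-1.23, SE 0.10) and near IL6 (-1.45, SE 0.21), and a rise near BCL3 (0.71, SE 0.09). The median of this list was 0.00 and its mean -0.08, and its test pointed lower. In BCR and MYD88 signalling, 36 of 200 were lower and 23 higher (36 and 26 adjusted over the list alone; camera, adjusted p = 0.920), with falls near TLR7 (-1.77, SE 0.20), in PLCG2 (-0.99, SE 0.11) and in LYN (-0.57, SE 0.07) and a rise in PIK3AP1 (1.17, SE 0.14).

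**Figure D3:**
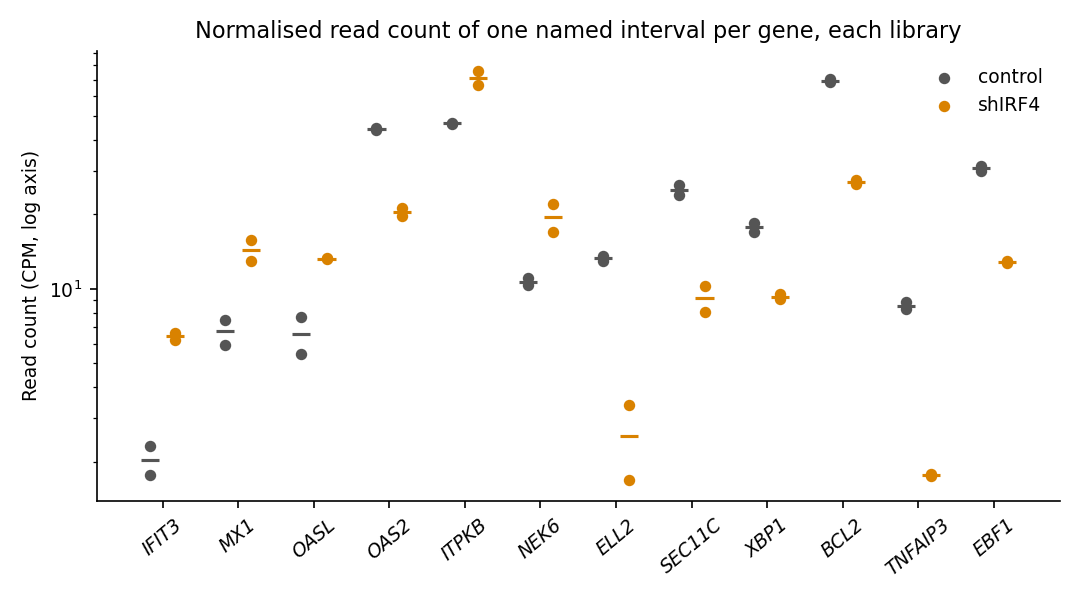
CPM (y axis, log scale) in each library at 1 named interval per gene (x axis), with control libraries in grey, shIRF4 libraries in orange and a bar at each group mean (n = 2). IFIT3, MX1, OASL, ITPKB and NEK6 lie higher in both shIRF4 libraries, and OAS2, ELL2, SEC11C, XBP1, BCL2, TNFAIP3 and EBF1 lie lower.

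The remaining lists did not pass. MHC class II had 5 of 48 intervals higher and 7 lower (6 and 7 adjusted over the list alone; camera, adjusted p = 0.462), with a fall in its activator CIITA (-1.08, SE 0.17) and near HLA-DPB1 (-1.10, SE 0.14) and a rise near HLA-DQA1 (1.06, SE 0.16). HLA genes resemble their paralogs, so reads there are less certain to be placed. The fall at HLA-DOB (-0.57, SE 0.15) was lost without control replicate 2 (adjusted p = 0.126), without shIRF4 replicate 1 (adjusted p = 0.0815) and in DESeq2 (adjusted p = 0.235). MYC and cell cycle genes had 6 of 91 higher and 7 lower (the same numbers adjusted over the list alone; camera, adjusted p = 0.199), with rises in CCND3 (1.09, SE 0.17) and near ODC1 (0.77, SE 0.11) and falls near CCND2 (-0.82, SE 0.14) and in MYBL2 (-0.55, SE 0.07). Among p53 targets 7 of 45 were higher and 3 lower (the same numbers adjusted over the list alone, with adjusted p = 0.151 by camera). Intervals rose near FAS (0.54, SE 0.08) and ZMAT3 (0.67, SE 0.13). The ZMAT3 change fell to 0.37 without shIRF4 replicate 1, and its call was lost. Falls in CDKN1A (-0.46, SE 0.09) and near RRM2B (-0.56, SE 0.12) were lost in DESeq2 (adjusted p = 0.0880 and 0.109). The p53 list passed as higher when intervals were assigned to the nearest gene end (adjusted p = 0.0359). The unfolded protein and stress response had 10 of 40 lower and 3 higher (11 and 3 adjusted over the list alone; camera, adjusted p = 0.562; adjusted p = 0.0295 by fry), with falls near HERPUD1 (-0.77, SE 0.13) and HMOX1 (-0.66, SE 0.12) and in ATF3 (-0.82, SE 0.14).

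Genes of other cell types also changed at single intervals, and none of their lists passed. T cell markers had 7 of 38 lower and 3 higher (the same numbers adjusted over the list alone; camera, adjusted p = 0.920), with falls near CD8A (-1.61, SE 0.19) and in CD28 (-0.87, SE 0.15); the median was 0.08, the mean -0.03, and the test pointed higher. NK cell markers had 4 of 28 lower and 2 higher (the same numbers adjusted over the list alone, with adjusted p = 0.920 by camera). The lower intervals lay at NCR1 (3) and NKG7 (1), both on chromosome 19. The rises near PRF1 (0.82, SE 0.19) and EOMES (0.96, SE 0.23) did not pass in DESeq2 (adjusted p = 0.128 and 0.148). Myeloid markers had 10 of 44 lower and 2 higher (11 and 2 adjusted over the list alone; camera, adjusted p = 0.562); CD33, which held 9 of the lower intervals (-0.43, SE 0.08 at 51181057 to 51186864), lies on chromosome 19 beyond 48 Mb, and CEBPA (-0.51, SE 0.09; adjusted p = 0.0503 in DESeq2) lies elsewhere on that chromosome. Epithelial and fibroblast markers had 4 of 36 in each direction (5 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.872), with falls near COL3A1 (-2.22, SE 0.27) and in CDH1 (-0.75, SE 0.13); the median was 0.01, the mean -0.01, and the test pointed higher. Housekeeping genes had 4 of 48 higher and 3 lower (3 and 1 adjusted over the list alone; camera, adjusted p = 0.0635), with rises near B2M (0.57, SE 0.09) and YWHAZ (1.32, SE 0.29; adjusted p = 0.0695 in DESeq2). This list passed as higher with library totals only (adjusted p = 0.0394), with abundance-trended offsets (adjusted p = 0.0495) and without control replicate 1 (adjusted p = 0.0327).

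Changed intervals lay mostly away from gene ends. Of the intervals not called, 20.4% were within 1 kb of the end of a protein-coding gene, against 11.8% of the higher (odds ratio 0.521, Fisher's exact p = 3.91e-57, two-sided) and 6.03% of the lower intervals (odds ratio 0.251, with a still smaller p). IFIT3, OASL and IRF9 were among the genes with a higher gene-end interval, while the named intervals of ELL2, BCL2, EBF1 and FOXP1 lay more than 1 kb from an end. The odds ratio of higher intervals was 0.874 without shIRF4 replicate 1 (Fisher's exact p = 0.0113) and 0.245 against a 1.5-fold change, at which the odds ratio of lower intervals was 0.123; neighbouring intervals are not independent, so these p-values are too small.

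Read counts on chromosome 19 fell over whole stretches in shIRF4. From 48 Mb to the chromosome end, 919 of 2298 intervals were lower and 17 higher, with a median log2 fold change of -0.33, against 0.02 over the other chromosomes apart from Y and 0.02 on the rest of chromosome 19. Between 1 and 3 Mb, around TCF3, 161 of 432 were lower and 3 higher (median -0.25). Against the control mean, the median of this stretch was -0.31 in shIRF4 replicate 1 and -0.14 in shIRF4 replicate 2. Against the control mean, the median over the distal stretch was -0.42 in shIRF4 replicate 1 and -0.14 in shIRF4 replicate 2, so that the libraries of this group differed in size but not in direction. The limits of both stretches were chosen after the values were seen. Bins as low as the weakest bin of the distal stretch were not confined to chromosome 19. In a scan added after the data were examined, of 1335 bins of 1 Mb with 20 or more intervals outside chromosome Y, 88 had a median at or below -0.18, the highest median of a bin in the distal stretch. Of these, 14 were on chromosome 19 and 74, out of 1287 bins, on 21 other chromosomes. Such bins thus made up a larger share on chromosome 19. The limit is weaker than the distal stretch's median of -0.33, and runs of adjacent low bins on other chromosomes were not searched for. The lowest lay on chromosome 2 at 129 Mb (24 intervals, 18 lower and 0 higher, median -0.84). SPIB and CD33 lie in the distal stretch. Without chromosomes 19 and Y, 15603 of 67320 intervals were called (10514 lower, 5089 higher).

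**Figure D4:**
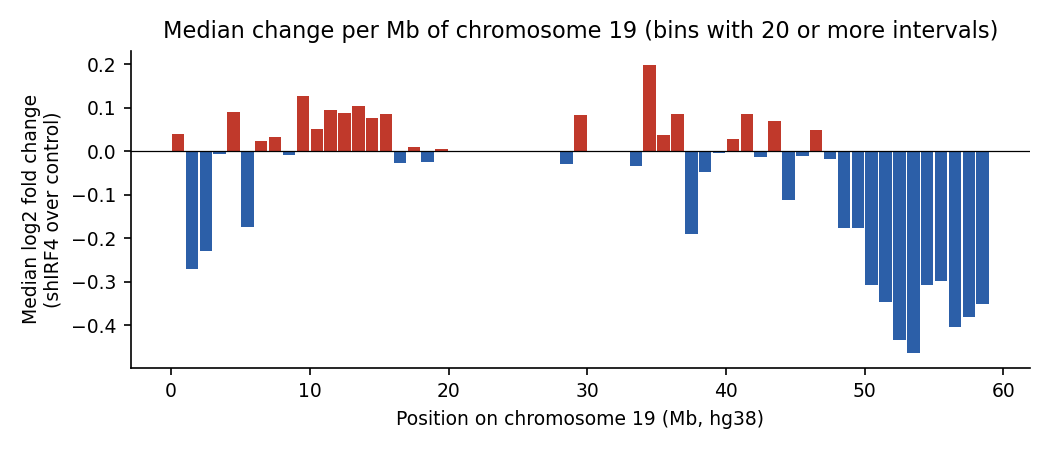
Median log2 fold change (shIRF4 over control, y axis) of the intervals in each 1 Mb bin of chromosome 19 (x axis, position in Mb, hg38), for bins with 20 or more intervals. The bins from 48 Mb onward lie between -0.18 and -0.46, and those from 1 to 3 Mb at -0.27 and -0.23.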

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

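The alternatives that thin the libraries, omit chromosomes 19 and Y, restrict intervals to 5 kb, trend offsets by read density, count the control pair as 1 sample, test against a 1.5-fold change or assign by the nearest gene end were chosen after the data were examined. More intervals were lower than higher in every alternative run. The count of changed intervals (16639) moved to 4570 in DESeq2, 2886 against a 1.5-fold change and 10042 at a threshold of 0.01, and lay between 9012 and 19960 with 1 library left out, where a lone library is assumed to vary like the other group. Higher intervals (5301) moved to 856, 467 and 2594 in the same order, and to between 2618 and 6839; lower intervals (11338) moved to 3714, 2419 and 7448, and to between 6394 and 13121. All 4570 DESeq2 calls were also edgeR calls. The fitted dispersion may account for the gap, since its median was 0.0297 in DESeq2 and the trended value in edgeR 0.00226, and 79.7% of intervals had a DESeq2 gene-wise dispersion near 0; the cause was not tested further. With the control pair as 1 sample, 9726 of the lower and 3853 of the higher intervals were called again. IRF4 intervals called (2) were 1 in DESeq2, 0 against a 1.5-fold change and 1 to 3 with 1 library left out. The replicate numbers did not pair the libraries (correlation of same-numbered deviations -0.0238), and the replicate block gave 16612 calls and also called the IRF4 interval at 398455 (adjusted p = 0.0479), as did omission of chromosomes 19 and Y (0.0499). Scaling by totals shifted the median log2 fold change by 0.05.

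Lists past the threshold (3) were 0 with an estimated correlation, 5 by fry (which tests against no change and not against the other intervals, so that its count answers another question), 1 at gene ends only and 2 to 5 with 1 library left out. The GCB signature gave adjusted p = 0.552 (estimated correlation), 0.224 (fry), 0.317 (gene ends only) and 0.637 (counts summed per gene), and 0.000544 to 0.0397 with 1 library left out. The plasma cell program gave 0.376 (estimated correlation), 0.0738 (within 50 kb) and 0.348 (gene ends only), and 0.00819 to 0.0789 with 1 library left out. The interferon response was lost with the estimated correlation (0.376) alone and gave 0.000851 to 0.00405 with 1 library left out. The estimated correlation was -0.00915 for the interferon response and -0.00562 for the plasma cell program, below the preset 0.01. This argues against a higher correlation between intervals as the cause of those 2 losses. For the GCB signature it was 0.0553, above the preset value. Otherwise the cause of these losses was not tested, except that gene ends hold fewer intervals.

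Lists turned direction as follows, and none passed in the turned direction; the cause was not tested. At gene ends only these were NF-kB targets, cell death regulators and T cell markers (adjusted p = 0.317 each), B cell identity (0.989) and the unfolded protein response (0.553). Others were NF-kB targets by nearest gene end (0.937) and without shIRF4 replicate 2 (0.926), BCR and MYD88 signalling within 50 kb (0.991), with abundance-trended offsets (0.946), without control replicate 1 (0.884) and without shIRF4 replicate 2 (0.603), and B cell identity without chromosomes 19 and Y (0.854). T cell markers turned by fry (0.181) and with abundance-trended offsets (0.946). NK cell markers turned with abundance-trended (0.946) and density-trended offsets (0.888), without chromosomes 19 and Y (0.394), without control replicate 1 (0.884) and without shIRF4 replicate 1 (0.659). Myeloid markers turned without chromosomes 19 and Y (0.156), with summed counts (0.637) and without shIRF4 replicate 1 (0.826), and epithelial and fibroblast markers by fry (0.399) and with summed counts (0.707). With 1 library left out, the smallest adjusted p of 4 of these lists came from fits that kept their direction (lower): NF-kB targets 0.417 and BCR and MYD88 signalling 0.233 without shIRF4 replicate 1, and NK cell markers 0.598 and myeloid markers 0.105 without shIRF4 replicate 2. Cell death regulators passed as lower in some other alternatives (0.0220 by fry), and the unfolded protein response passed as lower by fry (0.0295).

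Of 80 named called intervals, 8 were lost in DESeq2, 32 against a 1.5-fold change, 3 without shIRF4 replicate 1, and 1 each without control replicate 1 and 2; none turned direction in the alternatives run. The lower share of changed intervals at gene ends kept its direction in all alternatives (odds ratio 0.245 to 0.874 for higher and 0.123 to 0.330 for lower intervals). Depth limits small changes: 37% of simulated 1.5-fold changes were recovered. GC-content offsets, alone or with the replicate block, and all motif alternatives were not run.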

Other observations

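The tests of library totals, thinned counts, duplicate removal, density differences, interferon gene ends and other splits of the libraries were chosen only after the results they measure were seen; the others were fixed beforehand. Summed over all intervals of a gene, 1087 of 16121 genes were higher and 2161 lower (edgeR, adjusted over genes). The genes in this paragraph were chosen after their values were seen, among genes with at least 5 intervals outside the lists and chromosomes 19 and Y. LY6E, an interferon-inducible membrane protein gene, had the smallest p among the higher genes, with a rise of 0.97 (SE 0.06, adjusted p = 8.72e-08), from 55.9 and 56.1 CPM in the control libraries to 115 and 104 in the shIRF4 libraries. At LY6E, 3 of 6 intervals were higher, the strongest on chromosome 8 at 143023916 to 143027641 (1.17, SE 0.07). CD96, a receptor gene of T and NK cells, rose by 0.62 (SE 0.07) with 6 of 11 intervals higher, and NRP2, a semaphorin coreceptor gene, by 0.47 (SE 0.05) with 5 of 10. EZH1, a histone H3 methyltransferase gene of Polycomb complexes, changed by -0.99 (SE 0.06) with 5 of 7 intervals lower. MYRIP (-1.13, SE 0.06), VSNL1 (-0.79, SE 0.05), TRERF1 (-0.78, SE 0.05) and RHEX (-0.77, SE 0.05) were also lower, RHEX at 14 of 19 intervals. RNF213, a ubiquitin ligase gene induced by interferon, was lower (-0.68, SE 0.05) with 12 of 20 intervals lower, opposite to LY6E.

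Within the interferon list, the 20 gene-end intervals had a median log2 fold change of 0.41 and the other 44 a median of 0.12 (two-sided permutation p = 0.0117). The intervals of a gene are not independent, so this p is too small.

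Over the distal stretch of chromosome 19, fewer copies in the shIRF4 cultures would move all intervals alike, apart from any capped by duplicate removal. The test fixed beforehand, the median of the 575 intervals with the most reads per kb, gave -0.11 (95% bootstrap interval -0.145 to -0.0865). That value lies between the bounds set for a copy loss and for a smaller share of background reads, and the shIRF4 libraries lay on either side (-0.17 in replicate 1 and -0.04 in replicate 2, against the control mean), so neither could be decided by it. In a comparison added afterwards, these densest intervals lay 0.28 above the sparsest (0.31 in shIRF4 replicate 1, bootstrap interval 0.288 to 0.357, and 0.16 in replicate 2, 0.125 to 0.194), against 0.03 on other chromosomes (0.08 and -0.05), which argues against copy loss as the whole cause. Copy loss in part or in whole, a smaller share of background reads, and an effect of silencing IRF4 may each remain and cannot be told apart.

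The control libraries differed beyond sampling noise mainly at high counts: the chi-square per degree of freedom was 0.979 at summed counts under 100 and 3.21 at 2000 or more. Duplicate removal that saturates where reads are densest is a candidate explanation, since among the 50 intervals with the most reads per bp the shallower library had the higher CPM in 88% in the control group and 98% in the shIRF4 group. A single control library deposited under both names was tested on summed counts of 400 to under 2000 outside the densest intervals. These still differed (1.05 per degree of freedom over 9361 intervals, chi-square p = 0.000817). So small an excess could also come from saturation left outside the densest intervals, so the test does not decide this. Whether the control libraries are preparations of the same culture stays open, and no biological explanation was tested.

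More intervals were lower than higher, and 3 technical explanations were set against it. With library totals in place of TMM factors 9926 intervals were lower and 7181 higher (58.0% lower, against 68.1%), so a large part of the excess goes with the scaling. The direction held in the scalings run. All of them are relative to the reads of the same libraries, so they cannot show that it holds under every scaling. With all libraries thinned to the smallest total 69.1% were lower, and outside stretches with more than 30 intervals within 500 kb 66.0% (69.3% inside), which argues against depth and against those stretches as the whole cause. The share of background reads per library, a shared culture within a group and an effect of silencing IRF4 were not tested and stay open. The 4 libraries allow 3 splits into pairs, too few for a share under 0.05; the real split, 1 of the 3, gave 16639 called intervals and the highest of the others 0 (edgeR; 224 at an unadjusted p under 0.05, against 24888 for the real split).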
